A study of Homo sapiens with 8 samples.

How the data were processed

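The series measured N4-acetylcytidine (ac4C) in RNA of the human osteosarcoma cell lines 143B and HOS, of which 143B was derived from HOS. Per the labels, RNA was extracted with TRIzol, mRNA was enriched by poly(A) selection and fragmented, fragments bound by an anti-ac4C antibody were recovered (acRIP), and libraries were made with an NEBNext kit. The labels list 8 samples, 1 for each combination of cell line, genotype (NC, the control, or sgNAT10, the NAT10 knockout) and assay (acRIP or input). The deposited values used here are counts: raw read counts per genomic peak interval, in 1 table per cell line, with the same 31395 intervals in both tables. Each table held a count column for NC and a count column for sgNAT10, and neither column name gave the assay. They were taken as the 4 acRIP libraries because the tables are named as RIP counts. Input libraries were not used here. The tables also held 7 blank columns and no interval on the mitochondrial chromosome. The authors' processing notes name the build GRCh38 and the tools FastQC, STAR, SAMtools and deepTools, without versions or roles. The peak caller, the counting tool, the strand setting and the handling of reads that map to several places were not given in the sources used here. Whether interval starts count from 0 or from 1 was not given either, so positions are printed as the tables hold them.

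Each interval was compared with the gene spans of a GRCh38 gene table of 59792 genes, which holds no strand and no exons. A peak was assigned to the protein-coding gene it overlapped if there was exactly 1, with readthrough symbols set aside, and otherwise to the single annotated gene it overlapped. By this rule 19107 peaks were assigned to 9102 genes, 705 overlapped several genes and stayed unassigned, and 11583 lay outside annotated genes. Gene values are the sums of the assigned peaks. This rule and the use of gene sums were chosen after the tables were seen, because the plan fixed before the data were examined assumed counts per gene. The gene lists, the rule for named genes, the model and threshold of the main test and most of its alternative settings were fixed before the data were examined. The use of that test on peaks was chosen after the tables were seen. The plan also held comparisons with input, which were not run. Alternative settings of the gene lists and others named below were chosen after.

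Totals over all peaks ranged from 20107718 counts (143B NC) to 24785306 counts (HOS NC). These totals cover peaks only and are not the sequencing depth. Counts were scaled with TMM factors, which ranged from 0.729 to 1.26. The 143B library labelled sgNAT10 stood apart from the others: its Spearman correlation across peaks was 0.718 with 143B NC, 0.695 with HOS NC and 0.583 with the HOS library labelled sgNAT10, against 0.803 to 0.865 among the other libraries. Relative to TMM, DESeq2-type size factors added -0.09 to every log2 shift in 143B and -0.16 in HOS, upper quartile factors added 0.21 and -0.09, and library totals alone added 0.35 and 0.59. No spike-in is named in the labels and inputs were not used here, so a loss of ac4C shared by all RNA cannot be seen, and a shift in acRIP counts mixes RNA level with enrichment.

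The change between genotypes was tested with the edgeR quasi-likelihood test on peaks, with cell line as a block and genotype as the tested term, after filterByExpr (minimum count of 10, minimum total of 15), with Benjamini-Hochberg adjustment and a threshold of 0.05. The design left 1 residual degree of freedom, since each cell line and genotype has 1 library and the 2 lines are the only repeats. The DESeq2 Wald test and limma-trend were run on the same design. Within a line there is no test: the shift is the difference in log2 CPM (prior count of 1), and its interval is a 95% interval for counting error only, computed from exact conditional binomial bounds or, for single counts, exact Poisson bounds. Reads without molecular identifiers are not independent molecules. Tested on simulated data with the estimated dispersion of 0.281, the peak test recovered 0% of peaks changed 2-fold, 0% of those changed 4-fold and 13% of those changed 8-fold, and on gene sums (dispersion 0.254) 47.5% of those changed 8-fold.

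Of 34 gene lists, 26 had at least 5 members among the 8064 gene sums tested. For each list and line, the median shift was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart when its median lay outside the middle 95% of the random lists. This rule was chosen after the tables were seen. Data were also simulated for lists of 20 genes, with the spread of shifts among genes set to 1 (log2). In these data, 0 of 20 lists without a change, 9 of 20 lists changed 1.5-fold and 17 of 20 lists changed 2-fold lay above that range. Members of a real list may move together, and how often such lists leave the range without a change was not tested. The simulation therefore gives no false call rate for the lists used here. Across lines, limma camera was run with a preset correlation of 0.01 and with an estimated correlation, adjusted over the 26 lists. The lists with fewer members were not tested: ac4C writer and cofactors (NAT10, DKC1 and FBL measured), blood cell markers (CD68), epithelial markers (CDH1, KRT8 and KRT18), inflammatory NF-kB targets (NFKBIA, NFKB1 and IL1A), metalloproteases (MMP1, ADAM9, ADAM10 and ADAM12), p53 targets (BBC3 and SUSD6), ribosomal RNA (RNA45SN1, RNA45SN2 and RNA45SN3) and mitochondrially encoded mRNAs (0 measured).

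Named genes are those with a symbol, a mean count of 100 or more and no pseudogene annotation: the 12 higher and the 12 lower in both lines, ranked by the smaller absolute shift of the lines. From each list, 2 to 4 members with the largest smaller shift in the direction of the list's median are named. Where the medians of the lines had opposite signs, members with those signs were named, a choice made after the data were seen. NAT10, ATF4, ASNS and YTHDC1 are always named. Genes on the Y chromosome are not named. One gene that the rule would name is not reported here.

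A further list of 241 genes commonly covered by cancer sequencing panels was written from general knowledge, after peaks present in a single library had been seen. Of these, 151 were measured, in none of the lists above and not yet looked at. Alternatives covered the scaling, the count filter, the dispersion, the test, the threshold, the prior count, the peaks and genes used, thinning to the smallest total and the cell line block. Not run were ac4C enrichment over input, its change and its spread, the change of input RNA, the fit over all libraries, the relation to GC content and exonic length, lists matched on GC content, and the removal of mitochondrial genes, because inputs, a genome sequence and exons were not used here and no peak lay on the mitochondrial chromosome. Leaving out a library left no residual degrees of freedom, and leaving out a line leaves the values of the other line. Tools were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.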

Results

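The comparison asked how the RNA recovered with an antibody against N4-acetylcytidine (ac4C), a modified base written into RNA by the acetyltransferase NAT10, differed between NAT10 knockout and control cells of the osteosarcoma lines 143B and HOS. The values were raw read counts over 31395 peak intervals on GRCh38, with a median width of 135 bp. The 4 libraries comprised 1 per cell line and genotype, so no group had replicates and no test within a line was possible. Totals over the peaks were 20107718 counts in 143B NC, 22365529 in 143B labelled sgNAT10, 24785306 in HOS NC and 21132328 in HOS labelled sgNAT10. The median count per peak was 19, 29, 14 and 27 in the same order. Intervals given with values cover counting error only.

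The rRNA block on chromosome 21 held a large share of counts, and this share was lower in both libraries labelled sgNAT10. Of its 60 peaks, 31 lay between the rRNA repeats, and the handling of reads that map to several places was not given. The share is therefore one of counts in the block, and not of rRNA or of reads. The 60 peaks of the rRNA block on chromosome 21 (8205988 to 8446572) held 42.6% of counts in 143B NC and 34.0% in 143B sgNAT10, and 60.3% in HOS NC and 42.5% in HOS sgNAT10. The median log2 shift of these peaks, sgNAT10 over NC, was -0.69 in 143B and -1.10 in HOS, and 0% of them were higher in either line. The 18S rRNA, a known NAT10 substrate, had 1 peak (8438228 to 8438682), with 170427 counts in 143B NC, 131962 in 143B sgNAT10, 277789 in HOS NC and 173246 in HOS sgNAT10, shifts of -0.87 and -1.03. The 10 peaks in 28S rRNA had medians of -0.74 and -1.15, so the 18S peak lay 0.12 above them in HOS and at -0.13 relative to them in 143B, where the SD among 28S peaks was 0.06 and 0.13. Within the block, 8 peaks of 98 to 343 bp had nearly equal counts in each library despite their unequal widths. Counts were 144825 to 145952 in 143B NC and 125872 to 126243 in 143B sgNAT10. In HOS they were 258112 to 258409 in NC and 153266 to 153659 in sgNAT10. The peaks of the block may therefore not be separate measurements.

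Peaks with low counts were higher in the libraries labelled sgNAT10 of both lines, and peaks in long noncoding RNA genes and narrower peaks outside annotated genes had similar shifts. All 31395 peaks had median shifts of 0.28 in 143B and 0.36 in HOS, and the 21740 with a mean count under 50 had 0.54 and 0.53. The 3194 peaks in long noncoding RNA genes had median shifts of 0.57 in 143B and 0.66 in HOS, and the 11124 peaks under 1000 bp outside annotated genes had 0.57 and 0.56. The 15355 peaks in protein-coding genes had -0.04 and 0.15, where the 143B median turns positive with upper quartile factors (0.12) and with library totals alone (0.26) and the HOS median is 0.00 with DESeq2-type size factors. They held 10.8% and 9.72% of counts in 143B NC and sgNAT10 against 10.5% and 15.7% in HOS. The 432 peaks of 1000 bp or wider outside annotated genes went from 20.5% to 26.5% of counts in 143B and from 9.85% to 17.4% in HOS. The 95% Wilson interval of every share reached at most 0.0216 percentage points to either side. It takes counts as separate, which may not hold in the rRNA block. Shares sum to a whole, so a lower share of the rRNA block raises the others.

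**Figure D1:**
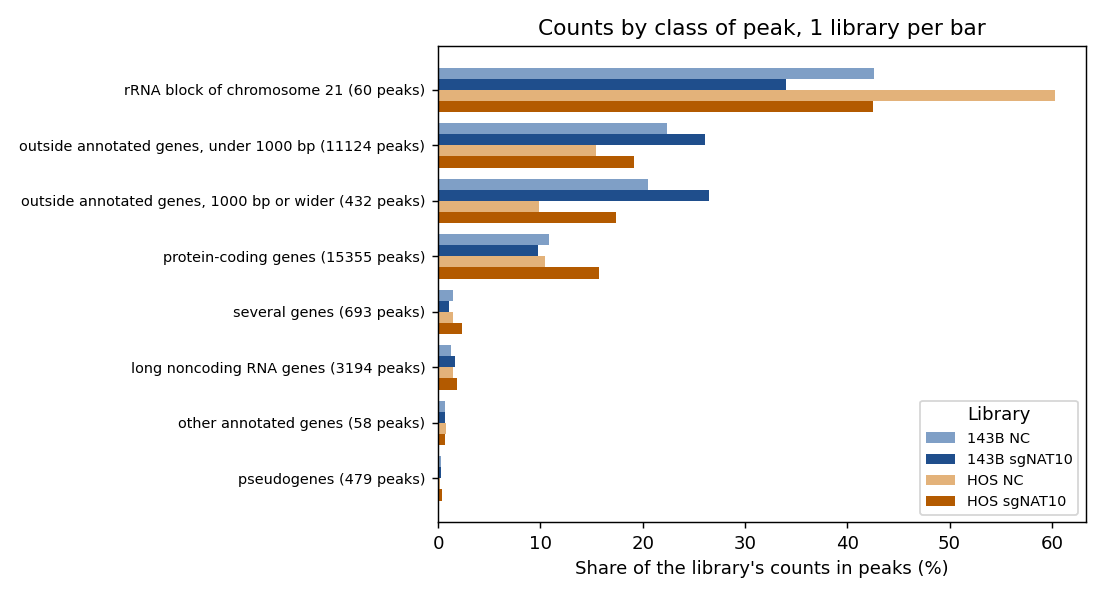
Share of each library's counts in peaks (%, horizontal axis) by class of peak (vertical axis), with 1 bar per library. The rRNA block held 60.3% of counts in HOS NC and 42.5% in HOS sgNAT10, and 42.6% and 34.0% in the 143B libraries.

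NAT10 itself (Gene ID 55226, chromosome 11, 34105629 to 34146908) had 1 peak, at 34146656 to 34146807 and 101 bp from an end of the gene. In HOS its counts were 180 in NC and 63 in the library labelled sgNAT10, or a normalised count (CPM) of 9.97 (8.57 to 11.5) and 2.74 (2.10 to 3.50), a log2 shift of -1.85 (-2.30 to -1.44). In 143B the counts were 65 in NC and 130 in the library labelled sgNAT10, or 3.27 CPM (2.52 to 4.16) and 4.63 (3.86 to 5.49), a shift of 0.50 (0.06 to 0.95) in the other direction. Across lines edgeR gave a log2 fold change of -0.79 (SE 0.79, adjusted p = 0.991). An edited gene may keep its mRNA level, and these are counts after immunoprecipitation. Scaled to library totals alone, the HOS shift was -1.27. Among peaks within 500 bp of a gene end, 2.71% had a lower shift than that of NAT10 in HOS and 41.6% in 143B.

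**Figure D2:**
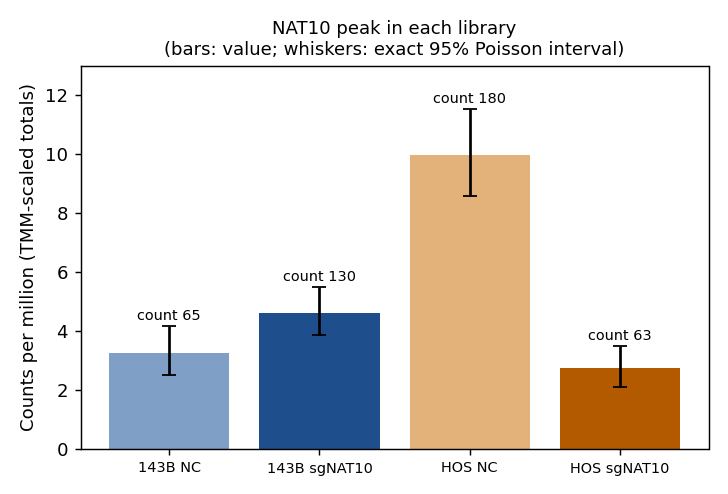
Normalised count of the NAT10 peak (vertical axis, CPM over TMM-scaled totals) in each of the 4 libraries, with exact 95% Poisson intervals as whiskers. The HOS library labelled sgNAT10 (2.74) lay below HOS NC (9.97), while the 143B library labelled sgNAT10 (4.63) lay above 143B NC (3.27).

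Across both lines, the genes whose peak sums were most clearly higher in the libraries labelled sgNAT10 included PAX8, a transcription factor of thyroid and kidney development (Gene ID 7849, highest peak on chromosome 2, 113234868 to 113236655). PAX8 went from 15 to 90 counts in 143B and from 19 to 661 in HOS, shifts of 2.02 (1.29 to 2.98) and 4.71 (4.11 to 5.51). The transcription factor gene ZBTB7C had shifts of 1.87 and 3.92, the somatostatin receptor gene SSTR5 2.29 and 1.61, the mucin gene MUC3A 1.84 and 1.39, the gene of the RNA-binding protein CPEB2 1.72 and 1.35, and RANBP17 1.69 and 1.31. The peak of CPEB2 and the peaks of PAX8, SSTR5 and MUC3A also overlap antisense or other noncoding genes. The other 6 of the 12 were LOC105369890 (1.71 and 1.53), LOC124901056 (1.48 and 1.47), LOC105374618 (1.51 and 1.34), LOC112268044 (2.04 and 1.33), LOC105372529 (1.49 and 7.17) and SKAP1 (1.39 and 7.74). PAX8 is also 1 of 18 genes commonly covered by cancer sequencing panels, among them ROS1, RET, ALK and ERBB3, that were all higher in HOS sgNAT10 (median shift 4.59) and had a median of -0.55 in 143B. These 18 were chosen after their values were seen. For LOC105372529 and SKAP1 the HOS shift rests on a single peak each, with 868 and 753 counts in HOS sgNAT10 and at most 2 counts in any other library.

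The lowest genes in both lines were led by MRTO4, a ribosome assembly factor (Gene ID 51154, peak on chromosome 1, 19259571 to 19259736). MRTO4 went from 111 to 39 counts in 143B and from 217 to 33 in HOS, shifts of -1.97 (-2.57 to -1.47) and -3.03 (-3.64 to -2.54). The nuclear receptor gene NR2F2 had shifts of -2.51 and -1.69, the TEAD cofactor gene VGLL3 -2.34 and -1.61, and CCN1, which encodes a secreted matrix protein, -1.72 and -1.58. The tubulin gene TUBA1C had -1.55 and -1.496, the peroxiredoxin gene PRDX1 -1.46 and -1.51, and SEC61A1, a channel subunit of the endoplasmic reticulum, -1.39 and -1.63. The others were ALDH18A1 of proline synthesis (-1.43 and -2.03), SMG5 of nonsense-mediated decay (-1.75 and -1.42), HCFC1 (-2.10 and -1.39), SLC35E1 (-1.64 and -1.44) and KIAA2013 (-1.51 and -1.42). Relative to TMM, the other scalings add between -0.16 and 0.59 to every shift, so the sign of each of these 24 genes was kept under all of them.

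**Figure D3:**
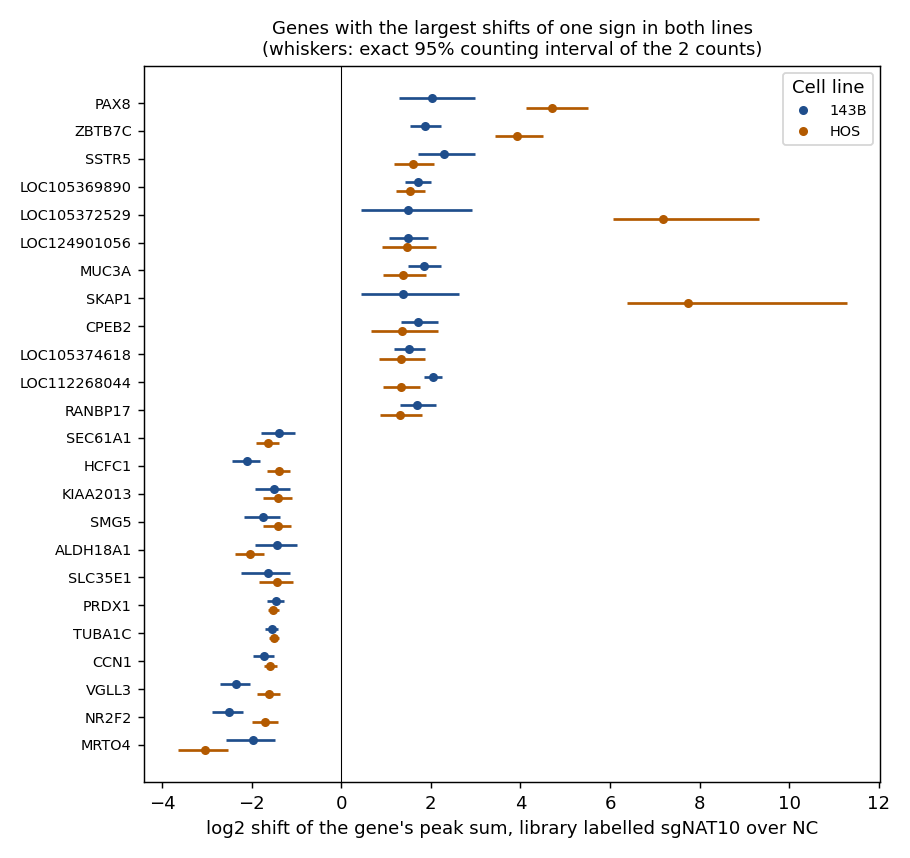
Log2 shift of the peak sum (horizontal axis, library labelled sgNAT10 over NC) of the 12 genes highest and the 12 genes lowest in both lines, with 143B and HOS as separate points and exact 95% counting intervals as whiskers. PAX8 lay at 2.02 and 4.71, and MRTO4 at -1.97 and -3.03.

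No gene or peak passed the test across lines. With edgeR, 0 of 24467 peaks were higher and 0 lower at an adjusted p of 0.05, the smallest adjusted p was 0.0548, and 945 peaks had an unadjusted p under 0.05. DESeq2 gave 0 peaks (500 at an unadjusted p under 0.05) and limma-trend 0 (1090). For gene sums, edgeR gave 0 of 8064 (308 at an unadjusted p under 0.05), DESeq2 0 (204) and limma-trend 0 (364), with an adjusted p = 0.991 for PAX8 (log2 fold change 3.35, SE 0.99) and for MRTO4 (-2.64, SE 0.77) in edgeR. Without the cell line block the count was also 0, with 499 at an unadjusted p under 0.05. Among the 5938 peaks with a mean count of 100 or more, 5 were higher and 1 was lower. The higher peaks were chosen for naming after their values were seen, and the lower peak is not named. The peak in LOC105376413 (chromosome 10, 11671136 to 11671244) went from 9886 to 62995 counts in 143B and from 20748 to 44766 in HOS (log2 fold change 1.72, adjusted p = 0.0132, higher in 2 of 2 lines). The remaining higher peaks, in LINC00351, SKAP1 and LOC105372529 and at 17922616 to 17922721 on chromosome 3, had 0 counts in both NC libraries, 1 to 3 in 143B sgNAT10, and 445, 753, 868 and 773 in HOS sgNAT10.

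Line by line, many peaks differed by at least 2-fold, and whether the lines shared more higher peaks than independence would give depended on the prior count and the count filter. In 143B, 4927 of 24467 peaks were higher and 5229 lower by 2-fold or more in the library labelled sgNAT10, and in HOS 5968 were higher and 2138 lower. Both lines shared 1409 higher peaks, where independent lines would give 1202 (714 against 717 with a prior count of 5, and 56 against 75.3 with a mean count of 100 or more), and 384 lower peaks, where independence would give 457. A further 1517 peaks were lower in 143B and higher in HOS, against 1276 under independence (471 against 230 with a mean count of 100 or more), and 424 were higher in 143B and lower in HOS, against 430. With library totals alone the split moved to 7308 higher and 3830 lower in 143B, 10744 and 611 in HOS, and 3612 and 63 shared.

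The position of a peak along its gene separated the lines. Among peaks of protein-coding genes with a mean count of 50 or more, the 1292 within 500 bp of an end of the gene span had a median shift of 0.68 in 143B, with 72.5% higher, and -0.61 in HOS, with 18.2% higher. The 5074 peaks farther from both ends had -0.89 in 143B, with 26.1% higher, and -0.02 in HOS, with 49.5% higher. Within the same gene, peaks near an end exceeded the others by a median of 0.88 in 143B, in 339 of 426 genes, and by 0.05 in HOS, in 236 of 426. VIM, the gene of the intermediate filament vimentin, had 4 peaks with 143B shifts of -1.90, -1.51, -1.04 and 1.38 in order along chromosome 10, and HOS shifts between -0.08 and 0.10. TFRC, the transferrin receptor gene, had 1 peak at 1.92 and the others between -1.45 and -1.09 in 143B, and all of its peaks between -3.29 and -2.21 in HOS. The annotation used gives no strand, so the ends were not assigned to the start or the finish of transcripts, and these genes were chosen after their values were seen.

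**Figure D4:**
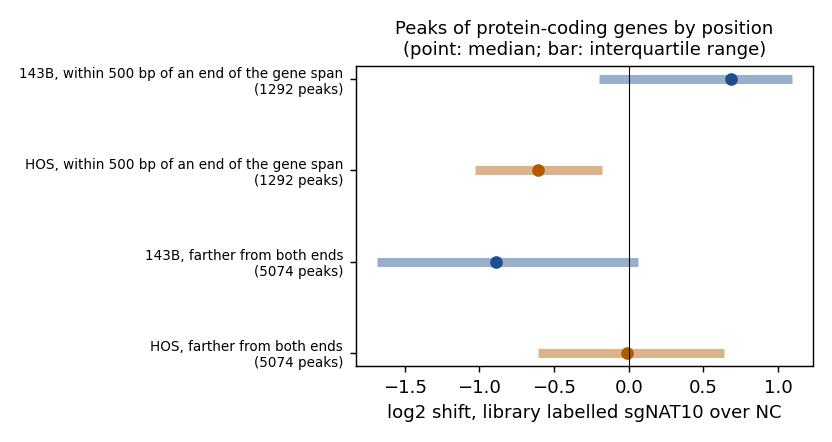
Log2 shift of peaks of protein-coding genes (horizontal axis, library labelled sgNAT10 over NC) by line and by distance to the nearer end of the gene span, with medians as points and interquartile ranges as bars. Peaks within 500 bp of an end had a median of 0.68 in 143B and -0.61 in HOS, and the others -0.89 and -0.02.

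Genes of the proteasome, oxidative phosphorylation and translation stood apart from matched genes, in opposite directions in the lines. Of 22 proteasome genes, which encode the protease that degrades tagged proteins, 20 were higher in 143B (median shift 0.96, percentile 100 of random lists) and 22 lower in HOS (-1.04, percentile 0), with PSMB5 at 1.31 and -1.32, PSMB4 at 1.14 and -1.11, PSMD1 at 1.05 and -1.48 and PSMC5 at 0.96 and -0.97. Of 48 nuclear-encoded genes of oxidative phosphorylation, 43 were higher in 143B (0.84, percentile 100) and 47 lower in HOS (-0.60, percentile 0.19), with cytochrome c, CYCS, at 2.48 and -1.49, COX7B at 1.57 and -1.38, ATP5PB at 1.61 and -0.95 and COX7A2 at 1.06 and -1.22. Of 31 translation factor genes, 20 were higher in 143B (0.39, percentile 99.9) and 27 lower in HOS (-0.56, percentile 1.32), among them EIF6 at 1.38 and -0.996 and EIF4A1 at 0.75 and -0.95. Of 73 cytosolic ribosomal protein genes, 67 were higher in 143B (0.58, percentile 100), while in HOS 70 were lower (-0.37) at percentile 5.14, within the range of random lists. FAU lay at 1.02 and -0.80 and RPL29 at 0.62 and -0.64. With library totals alone the HOS median turned to 0.22 for ribosomal proteins and 0.02 for translation factors, and was -0.01 for oxidative phosphorylation and -0.45 for the proteasome. In 143B, peaks near gene ends were higher in general, and the 143B percentiles were 99.2 to 100 for these 4 lists from peaks near ends and 99.3 to 100 from the others. From genes with all peaks under 300 bp, translation factors lay within the range of random lists in 143B (0.15, percentile 76.2) and in HOS (percentile 21.4), as did oxidative phosphorylation in HOS (percentile 11.3). In HOS, peaks near ends alone gave percentiles of 4.64 for the proteasome, 67.6 for oxidative phosphorylation, 42.8 for translation factors and 92.0 for ribosomal proteins, while peaks away from ends put ribosomal proteins at percentile 0.86, below the range.

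Cell cycle and cholesterol genes were lower in HOS. Of 11 G2/M genes, 10 were lower in HOS (-1.25, percentile 0.04) and 9 higher in 143B (0.997, percentile 99.5), with the spindle gene TPX2 at 1.33 in 143B and -1.25 in HOS and the ubiquitin-conjugating enzyme gene UBE2C at 0.53 and -1.62. The 143B percentile of G2/M was 92.2 from peaks near gene ends, 79.5 from the other peaks and 84.5 from genes with a mean count of 100 or more, and the HOS percentile was 9.97 from peaks away from ends. Of 18 G1/S and DNA replication genes, 17 were lower in HOS (-1.16, percentile 0) and 11 higher in 143B (0.43, percentile 95.3), with PCNA, the sliding clamp of DNA polymerase, at 0.65 and -2.06 and FEN1 at 1.08 and -1.69. The 143B percentile of this list was 97.7 from genes with a mean count of 100 or more, above the range. It was 39.7 from peaks near gene ends and 56.5 from the other peaks. Of 6 cholesterol synthesis genes, 5 were higher in 143B (1.55, percentile 99.9) and 6 lower in HOS (-1.58, percentile 0), with squalene synthase, FDFT1, at 1.61 and -1.40 and the regulator SREBF2 at 1.14 and -0.60. The 5 replication-dependent histone genes were lower in both lines (-0.70, percentile 46.8, in 143B and -1.74, percentile 0, in HOS), with H4C2 at -1.20 and -1.82, H2AC11 at -0.93 and -2.00 and H4C8 at -0.70 and -1.71.

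Protein folding, MYC target, ribosome assembly and glycolysis genes were lower than matched genes in HOS. Their 143B percentiles, between 70.8 and 94.7, stayed within the range of random lists, and the difference between lines was not tested. Of 9 heat shock genes, 8 were lower in HOS (-1.87, percentile 0), with the chaperone genes DNAJA1 at -2.06, HSPH1 at -2.04, HSPE1 at -1.87 and HSPD1 at -1.496, and shifts of 0.63, 0.37, 1.28 and 0.44 in 143B, where the median was 0.37. Of 13 genes of the unfolded protein response, 11 were lower in HOS (-1.09, percentile 0.02) and 11 higher in 143B (0.50), with CALR at -1.97 and 0.64 and HSPA5 at -1.36 and 1.16. The HOS percentile of this list was 14.6 from peaks near gene ends. Of 18 MYC targets, 17 were lower in HOS (-1.19, percentile 0; 0.13 in 143B), of 24 ribosome biogenesis genes 23 (-1.09, percentile 0; 0.09 in 143B), and of 15 glycolysis genes 13 (-1.16, percentile 0; 0.17 in 143B). From genes with all peaks under 300 bp the HOS percentile of glycolysis was 5.20, within the range of random lists. NOLC1 lay at -1.41 in HOS and 1.32 in 143B, BOP1 at -1.17 and 0.80, PHB2 at -0.71 and 0.98, ODC1 at -0.86 and 0.88, and triosephosphate isomerase, TPI1, at -1.23 and 1.40.

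**Figure D5:**
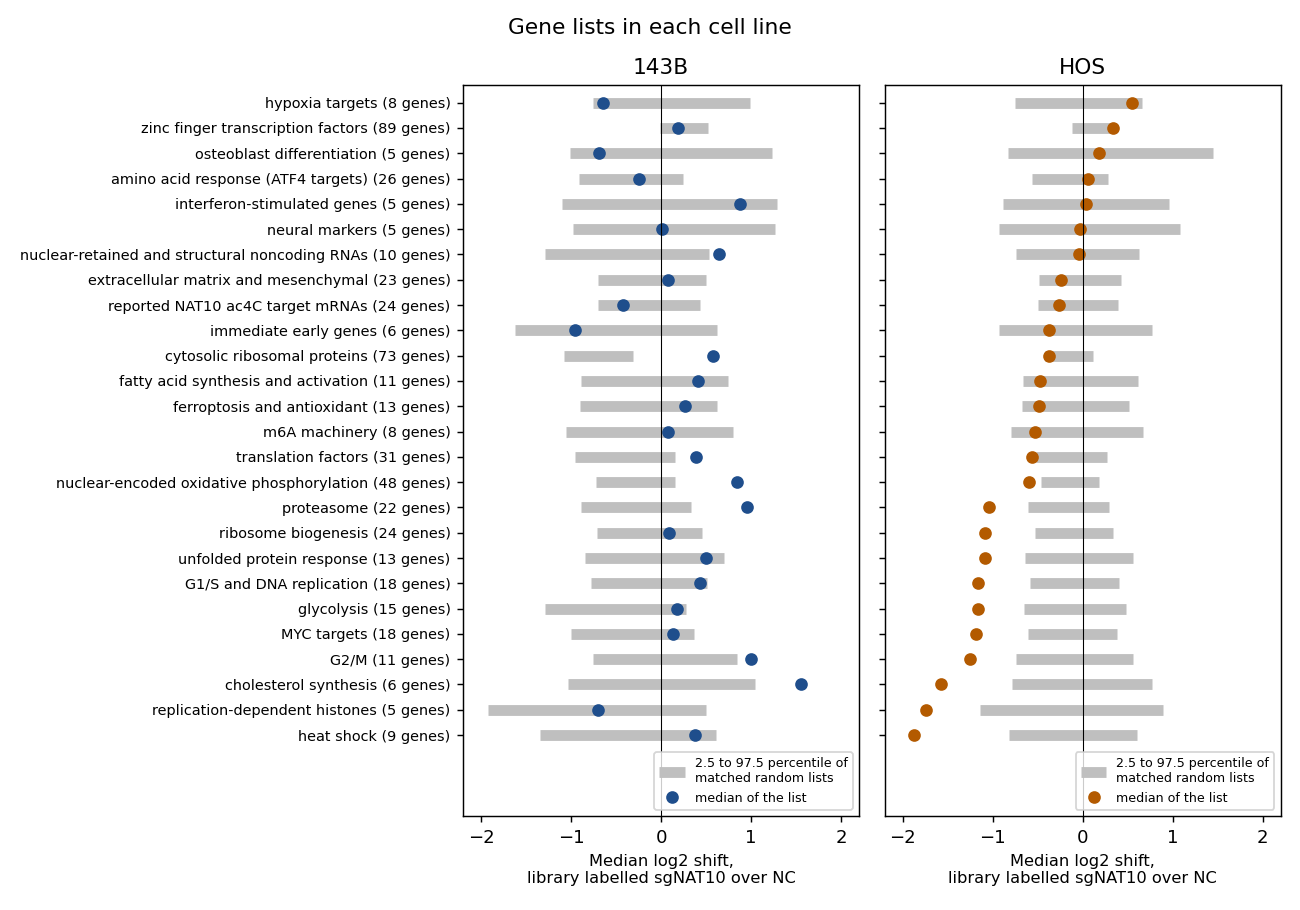
Median log2 shift of each of 26 gene lists (horizontal axis, library labelled sgNAT10 over NC) in 143B and HOS as points, with the middle 95% of matched random lists as grey bars. In 143B 7 lists lay above their bar and 0 below, and in HOS 0 lay above and 12 below.

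Genes reported to be ac4C targets of NAT10 did not stand apart from matched genes over all their peaks. From peaks near gene ends alone, a setting chosen after the data were seen, only 5 members remained. Their HOS median was -1.22 (percentile 1.32, below the range of random lists), with 2 higher and 3 lower. The same 5 were all higher in 143B (median 1.12, percentile 84.6, within the range). The list was drawn from general knowledge, and whether any member was reported from these samples was not established. Of 24 measured, 10 were higher and 14 lower in each line, with medians of -0.43 in 143B (percentile 15.2) and -0.26 in HOS (percentile 18.3), the latter turning positive with library totals alone. The kinase gene AKT1 lay at -0.59 and -0.95, lactate dehydrogenase, LDHA, at -0.27 and -1.91 and ACSL3 at -0.78 and -0.38, where LDHA in 143B and ACSL3 in HOS turn positive with library totals alone. ATF4, a transcription factor of the amino acid response, went from 624 to 388 counts in 143B and from 1801 to 1436 in HOS, shifts of -1.18 (-1.37 to -0.998) and -0.68 (-0.78 to -0.58). Its target ASNS, asparagine synthetase, went from 40 to 144 and from 175 to 468, shifts of 1.33 (0.84 to 1.89) and 1.06 (0.81 to 1.33), on a peak shared with the readthrough gene CZ1P-ASNS. YTHDC1, a reader of N6-methyladenosine, had -1.39 (-1.98 to -0.86) in 143B and 0.13 (-0.30 to 0.56) in HOS, the latter turning negative with DESeq2-type size factors. The adjusted p of each across lines was 0.991 in edgeR. The 26 genes of the amino acid response had medians of -0.25 (percentile 55.0) and 0.06 (percentile 83.5), with GPT2 at -3.19 and 1.33, ALDH1L2 at -2.21 and 2.40 and PSAT1 at -1.74 and 0.55. The HOS median of this list turned negative with DESeq2-type and with upper quartile factors, and the 143B median positive with library totals alone. Its HOS percentile was 100 from peaks near gene ends, 99.6 from genes with all peaks under 300 bp and 4.04 from peaks away from ends.

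Tested across lines with camera and a preset correlation, 6 of 26 lists were lower: ribosome biogenesis (adjusted p = 0.00864), replication-dependent histones (0.00864), MYC targets (0.0161), G1/S and DNA replication (0.0180), heat shock (0.0322) and immediate early genes (0.0468). In 143B, ribosome biogenesis (median 0.09), MYC targets (0.13), G1/S and DNA replication (0.43) and heat shock (0.37) had positive medians. For these lists the lower value rests on HOS alone, while histones (-0.70 in 143B and -1.74 in HOS) and immediate early genes had negative medians in both lines. Relative to matched genes, histones were not lower in 143B (percentile 46.8, median of random lists -0.66), and only 5 of the 44 listed histone genes were tested. With an estimated correlation camera called 0 lists (adjusted p = 0.967 for each of the 6). That setting rests on 1 residual degree of freedom, so it could hardly call any list, and its 0 calls decide nothing. The preset setting takes a correlation of 0.01 among members. Estimates were 0.68 for ribosome biogenesis, 1 for histones, 0.41 for MYC targets and for G1/S, 0.56 for heat shock and -0.07 for immediate early genes. Where members move together the preset p is too small, so the 6 calls do not establish a change either. Over all genes tested, 0 members of any list were called, and adjusted over the list alone 1 was, MRTO4 among the MYC targets (adjusted p = 0.0300, lower in 2 of 2 lines). The 6 immediate early genes had medians of -0.95 in 143B (percentile 19.4) and -0.37 in HOS (percentile 28.7), with EGR3 at -2.36 and -0.38, JUN at -1.24 and -0.35, MYC at -1.19 and -0.61 and KLF6 at -0.72 and -1.81, and the HOS values of the list, EGR3 and JUN turned positive with library totals alone.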

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

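Of the tests in this part, those of counting noise across genes and of genes with wide peaks were chosen only after the result was seen, while the others were set down before theirs, that of gene ends after 9 genes had been looked at and that of panel genes after the peaks of single libraries had been.

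The sign of the shift differed between the lines for NAT10 and for the 5 gene lists whose medians lay outside the middle 95% of random lists in both lines. Other lists also had medians of opposite sign but lay outside that range in at most 1 line. None of these differences was tested, because each arm has 1 library. Opposite signs were general among peaks near gene ends (medians of 0.68 in 143B and -0.61 in HOS). From those peaks alone, G2/M lay within the range in 143B (percentile 92.2). So did the proteasome (4.64), oxidative phosphorylation (67.6) and translation factors (42.8) in HOS, while cholesterol synthesis stayed outside in both lines. From peaks away from ends, the proteasome, oxidative phosphorylation and translation factors lay outside in both lines. The median log2 shift was 0.997 in 143B and -1.25 in HOS for G2/M genes. It was 1.55 and -1.58 for cholesterol synthesis genes. It was 0.84 and -0.60 for nuclear-encoded oxidative phosphorylation genes. It was 0.96 and -1.04 for proteasome genes. It was 0.39 and -0.56 for translation factor genes, where the HOS median turns positive (0.02) with library totals alone. NAT10, with 1 peak 101 bp from an end of the gene, had a shift of 0.50 in 143B and -1.85 in HOS. An edited gene may keep its mRNA level, so the 143B value does not by itself contradict the label.

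Among gene sums with high counts the shifts of the lines ran opposite, with Spearman rho = -0.386 over 1399 genes with a mean count of 300 or more and -0.247 over 3154 with 100 or more, but not over all 8064 genes (-0.018), where genes are not independent replicates. Counting noise would bring rho near 0 among the most counted genes, but it was -0.461 (-0.534 to -0.384) over 519 genes with a mean count of 1000 or more. Whether repeat-like and intronic peaks inside gene spans carry the pattern cannot be told apart from no relation among listed genes, since rho was -0.004 over 342 of them with an interval of -0.120 to 0.108. A candidate explanation is genes with wide peaks, since rho was -0.001 (-0.076 to 0.075) over 723 genes whose peaks were all under 300 bp and -0.425 over 676 genes with a wider peak, although this limit was chosen with its value in view and the test was first run with genes whose median peak width was under 300 bp, where rho was -0.299 over 1110 genes, and rho was 0.169 over 210 narrow-peak genes with a mean count of 1000 or more. A change of whole transcripts also stays open, since deviations of peaks from their gene's mean were unrelated between lines (rho = 0.0141, -0.049 to 0.074, 2571 peaks), as does a biological effect of NAT10 loss that differs between lines, which was not tested.

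Peaks of the same gene shifted unequally in 143B, with an SD within genes of 0.84 against 0.45 in HOS over 822 genes. The tables argue against counting noise of the peaks, since the SD stayed at 0.601 (0.510 to 0.689) among 236 peaks with a mean count of 1000 or more. In 368 genes with at least 3 peaks, without 9 genes already looked at, the peak with the highest 143B shift was the first or last along the gene in 72.8%, which exceeds the 52.9% that chance gives by 19.95 percentage points (15.1 to 24.4), against 58.2% for HOS, and in genes with all peaks under 300 bp it was 81.4% in 143B and 105 of 140 in HOS, where chance gives 58.4%. Reads moved toward one end of transcripts, as fragmented RNA after poly(A) selection may give, is therefore a candidate explanation, although the end was not identified without strand. A biological change of transcript ends or of ac4C along transcripts in the 143B cells labelled sgNAT10 was not tested and stays open.

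In the HOS library labelled sgNAT10 alone, 38 peaks had 100 or more counts and at most 3 in every other library, against 2, 1 and 0 such peaks in the others, and 17 of the 38 lay outside annotated genes. Those in genes with the most counts lie in LOC105372529 (868), SKAP1 (753), CTNNA3 (698) and NEDD9 (548), none of them picked as panel genes, while those in the panel genes ROS1, ALK, ERBB3, ERBB4, ESR1, NTRK3 and TMPRSS2 had 108 to 165, and the highest of all, on chromosome 7 at 54512191 to 54512376, had 1440 counts against 0 in HOS NC, at least 376-fold higher with a floor of 3 counts per library. A candidate explanation is DNA of a cancer gene panel in that library, but 151 panel genes not looked at before had a median HOS shift of 0.02 at percentile 87.6 of matched random lists, short of the bound set beforehand for this explanation, which was to lie above the middle 95% of the random lists, and since 78 were higher and 73 lower and resampling the genes gave percentiles from 31.8 to 99.1, the explanation cannot be told apart from its absence. The 18 panel genes picked from the pattern had a median of 15 peaks each, against 1.98 in matched random lists, but were chosen for their values and so test nothing. Transcription of these genes after NAT10 loss in HOS was not tested and stays open.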

How the results depend on the processing

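Alternatives on gene sums, peaks assigned to 1 gene, the rRNA block, cancer panel genes, peak width and position in gene lists, further list settings and the RLE and upper quartile scaling of per-line shifts, and the scaling of peak classes, were chosen only after the data were seen. The counts of 0 peaks across lines held under every other setting run, but with a mean count of 100 or more 5 peaks were higher and 1 lower, and with no filter 1 was lower; the cause was not tested. Line by line, a 1.5-fold threshold gave 7931 peaks higher in 143B, 9431 higher and 4116 lower in HOS, and 3477 higher and 1266 lower in both, as a looser threshold must. With a mean count of 100 or more, fewer peaks were counted: 669 higher and 2042 lower in 143B, 668 and 904 in HOS, and 56 and 219 in both. Library totals alone gave 10744 higher and 611 lower in HOS and 3612 and 63 in both, since they add 0.59 to every HOS shift, and a prior count of 5 gave 714 higher in both. The HOS shift of NAT10 was -1.27 with library totals. Lists above random lists in 143B numbered 4 from peaks over 500 bp from both ends of the gene, against 7, since cholesterol synthesis and nuclear noncoding RNAs had too few members there and G2/M lay within the range. With all peaks under 300 bp, 2 lists lay below in 143B (hypoxia targets and immediate early genes) and 2 above in HOS (hypoxia targets and the amino acid response). In HOS 1 list lay above from peaks within 500 bp of an end (the amino acid response), and 1 with a mean count of 100 or more (zinc finger transcription factors). Under alternatives, 452 list percentiles kept their side of the range, 15 no longer lay outside it and 12 newly did. The percentile of oxidative phosphorylation in HOS moved to 67.6 from peaks within 500 bp of an end, inside the range and above the middle of the random lists. Camera called 0 lists with an estimated correlation, a setting that rests on 1 residual degree of freedom and could hardly call any. Apart from that setting and the lists with too few members, the cause was not tested. The estimated dispersion, and not depth alone, limits what could be called: in simulated data at the same counts, 0% of peaks changed 4-fold were recovered at the estimated dispersion and 94.5% at a dispersion of 0.01. Enrichment over input, input changes, GC content, GC-matched lists, the fit over all libraries, mitochondrial gene removal and leaving out libraries were not run.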

Other observations

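The peak width classes, the peaks on mitochondrial pseudogenes and the example genes below were chosen only after the values were seen, and tests of rRNA peaks and of peaks with low counts were also run and are given as values without weighing.

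Nuclear noncoding RNAs were high in 143B, and the other lists of this part stayed within the range of matched random lists over all their peaks. Of 10 nuclear-retained and structural noncoding RNAs, 6 were higher in 143B (median 0.64, percentile 99.0) and 5 in HOS (-0.04, percentile 59.3), with NEAT1, the scaffold of paraspeckles, at 1.07 and 1.47 and SNHG1 at 1.09 and -0.45, where SNHG1 and the list turn positive in HOS with library totals alone. The 143B percentile was 76.2 from peaks near gene ends and 93.2 from genes with all peaks under 300 bp. Hypoxia targets had medians of -0.64 in 143B (percentile 4.41) and 0.54 in HOS (percentile 95.4), or percentiles of 2.41 and 98.7 from genes with all peaks under 300 bp, with the growth factor gene VEGFA at -0.87 and 1.01. Osteoblast genes had -0.69 (percentile 6.82) and 0.18 (percentile 43.2), with the bone transcription factor gene RUNX2 at -1.81 and 0.78. Zinc finger transcription factors, 89 genes, had 0.19 (percentile 30.7) and 0.33 (percentile 96.7, or 98.9 from genes with a mean count of 100 or more), with ZNF23 at 2.21 and 0.54 and ZNF792 at 1.69 and 0.69. Fatty acid genes had 0.41 (percentile 84.3) and -0.48 (percentile 8.66), with ACLY at 0.41 and -1.80. Ferroptosis and antioxidant genes had 0.27 (percentile 81.8) and -0.48 (percentile 9.39), with TXNRD1 at 0.44 and -0.95. Both lists turn positive in HOS with library totals alone, and from peaks away from gene ends their HOS percentiles were 2.26 and 1.07, below the range.

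Extracellular matrix genes had medians of 0.07 in 143B (percentile 64.4), negative with DESeq2-type size factors, and -0.24 in HOS (percentile 20.9), positive with library totals alone, or percentile 99.3 in 143B from peaks near gene ends, with CCN2 at 1.21 and -2.13 and TGFBI at 0.73 and -1.73. Genes of the m6A machinery had 0.08 (percentile 60.5) and -0.53 (percentile 11.4), with the same changes of sign, and YTHDF1 at 1.10 and -1.62. Interferon-stimulated genes had 0.87 (percentile 88.5) and 0.04 (percentile 49.8), the latter negative with DESeq2-type and upper quartile factors. Neural markers had 0.01 (percentile 32.5) and -0.03 (percentile 40.4), with signs that turn with DESeq2-type factors in 143B and with library totals in HOS.

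Lists with too few measured members are given by member, with the shift in 143B first. From the list called ac4C writer and cofactors, DKC1 lay at -1.09 and -1.12 and FBL at 0.06 and -0.54. Whether these genes act in ac4C was not established here. CDH1, 1 of the 18 panel genes that were all higher in HOS sgNAT10, lay at -2.40 and 6.78, KRT8 at -0.05 and -0.90, KRT18 at 0.64 and -0.66 and CD68 at -3.05 and 0.91. NFKBIA lay at 0.999 and 0.40, NFKB1 at 0.40 and -1.58 and IL1A at -1.89 and 1.95. MMP1 lay at -0.22 and -0.67, ADAM9 at -0.63 and -1.54, ADAM10 at 0.43 and -0.79 and ADAM12 at 0.53 and -0.48. BBC3 lay at -1.36 and 0.63 and SUSD6 at -0.94 and -0.58. RNA45SN1 lay at -0.62 and -1.08, RNA45SN2 at -0.49 and -1.04 and RNA45SN3 at -0.65 and -1.05.

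Wide peaks in protein-coding genes ran opposite in the lines. With a mean count of 100 or more, 612 peaks at least 2 times as wide as 300 bp had medians of -1.90 in 143B and 0.87 in HOS, and 508 of them were lower in 143B and higher in HOS. Their share of counts was 3.34% in 143B NC, 1.29% in 143B sgNAT10, 2.04% in HOS NC and 5.16% in HOS sgNAT10. Part of this share came from LOC102724250 and PCBD2, whose peaks lie on pseudogenes of mitochondrial genes. Over peaks of any width, LOC102724250 held 0.599% and 0.271% of counts in 143B NC and sgNAT10, and 0.439% and 0.841% in HOS. PCBD2 held 0.456% and 0.226% in 143B, and 0.227% and 0.474% in HOS. HMGA1, a chromatin architectural protein gene with a peak at 34244790 to 34246191 on chromosome 6, lay at -2.14 and 0.78, CMIP at -3.12 and 0.52, ADAMTS12 at -3.41 and 0.43 and SERINC2 at -1.80 and 0.41.

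The 59 peaks on pseudogenes of mitochondrial genes held 1.20% of counts in 143B NC, 0.591% in 143B sgNAT10, 0.749% in HOS NC and 1.48% in HOS sgNAT10, a shift of their sum of -1.37 in 143B and 0.40 in HOS. Of the 21740 peaks with a mean count under 50, 66.4% were higher in 143B and 68.5% in HOS, and 45.8% in both, against 45.5% from the product of the shares. The 18S peak lay -0.13 from the median of the 28S peaks in 143B (SD 0.13) and 0.12 from it in HOS (SD 0.06). The counts of 8 of the 31 peaks between the rRNA repeats varied by a CV of 0.263% in 143B NC and 0.103% in 143B sgNAT10. In HOS the CV was 0.032% in NC and 0.09% in sgNAT10.

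The 151 cancer panel genes not looked at before had a median shift of -0.48 in 143B (percentile 0.02, 46 higher and 105 lower) and 0.02 in HOS (percentile 87.6, 78 higher and 73 lower). Among genes of the panel list picked after their values were seen, FGFR2 lay at 2.47 in HOS, KIT at 2.23 and BRAF at 1.70, while CTNNB1 lay at -1.73, XPO1 at -1.64 and MSH6 at -1.34.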
